A study of Caenorhabditis elegans with 4 samples.

How the data were processed

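Samples were grouped by their titles into ChIP (2 libraries) and input chromatin (2 libraries) of a C. elegans strain with an NHR-76::GFP transgene at the L3 stage. Worms were cross-linked with 2% formaldehyde, and chromatin was sonicated and precipitated with anti-GFP antibodies, per the labels' protocols. No peak list belongs to an input sample.

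The authors deposited peak intervals on the WormBase WS220 build, per the file headers. The 2 replicate lists name their source as SPP through the irreproducible discovery rate (IDR) procedure, per the file headers and source fields, and the value deposited for each peak is a score whose scale is not stated. The score falls with the number in the peak's name (Spearman's rho of -0.997 in replicate 1 and -1.00 in replicate 2) and is limited at one highest value. The combined list names PeakSeq as its source, and the value deposited by the authors for each region is a q-value, per its attribute field. Comment lines in the combined file record a change of coordinates between builds (liftover) for 5 features; these lines were skipped and the feature lines were used. Versions, thresholds, the use of input and the pooling of replicates in the combined list are not given in the sources used here. The scores and q-values are the authors' and were used to describe, rank or filter peaks within their own list, and across lists in correlations over overlapping peaks and in a comparison of q-values between chromosomes at the same replicate 1 ranks. Since 2 programs made the lists, a difference between the combined list and a replicate list may come from the program. The fixed widths of 400 and 800 bp in the replicate lists set how often peaks overlap by chance, so each overlap is given with its chance level.

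Peaks were analysed with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and numba 0.67.0, and figures were drawn with matplotlib 3.10.9. Comparisons used the 6 nuclear chromosomes, and mitochondrial peaks are described separately. Replicate peaks were ranked by score, with ties in the order of the authors' peak numbers, and combined regions by q-value. Overlap required 1 shared bp. Chance overlap came from 100000 random circular shifts of one list along each chromosome, which keep widths and spacing (2000 shifts for each rank class), and tests were one-sided. The excess over chance is the number of overlaps above the chance mean, as a share of peaks that would not overlap by chance. Score correlations paired each replicate 1 peak with its best scoring overlapping replicate 2 peak and used 100000 permutations, two-sided. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only. Chromosome shares were tested with two-sided exact binomial tests against the chromosome's share of the span, taken as the largest peak end in any list, because no chromosome lengths of the build were used. Benjamini-Hochberg adjustment was applied within each family.

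The overlap test was tested on simulated lists of 21114 and 25332 peaks. With 5% of sites planted in common it recovered 5.28% ± 0.344 (SD over 5 runs), and with 30% it recovered 30.2% ± 0.337. With unrelated lists, 4 of 100 runs fell below 0.05. Simulated peaks were placed uniformly along chromosomes, with planted sites at the same centres in both lists. The clustering of the real peaks was not simulated, so these rates apply to evenly placed peaks.

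The named items were to be the 2 genes of the transgene, the genes at the 20 strongest combined regions found in both replicates, and members of 27 gene lists, and 11 sequence motifs were to be counted. The gene table at hand is of another assembly (WBcel235), and coordinates of the 2 builds were not mixed. The planned tests of promoters, gene lists, motifs, noncoding gene classes and scores by promoter were therefore not run, and the 20 regions are given by position, without the transgene's genes. Other regions named were chosen after their values were seen. The tests of list sizes, overlaps, score correlations and chromosome shares, a first set of alternatives and the naming rule were fixed before the data were examined. Further alternatives, the rank classes and the comparisons of wide regions, of chromosome I and of the chromosome middles were added afterwards. Alternatives covered the overlap required, the number of peaks kept from each list, each replicate on its own, the shift distance and the omission of chromosome I.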

Results

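Binding of the nuclear hormone receptor NHR-76 was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in Caenorhabditis elegans hermaphrodites of the third larval stage (L3), grown at 20 °C. The worms carried a transgene that expresses NHR-76 fused to green fluorescent protein (GFP), and anti-GFP antibodies recovered the fusion protein with its cross-linked DNA. There were 4 libraries, made of 2 ChIP libraries and 2 libraries of input chromatin that share their replicate numbers. The design addresses which genomic regions the fusion protein occupies at this stage. The files analysed are the authors' peak lists on the WormBase WS220 genome, with 1 list for each ChIP replicate and 1 combined list. The input libraries enter only through whatever use the authors made of them in peak calling. Read depth behind the peaks is unknown, so no interval on read counts can be given. The labels do not say whether the replicates came from separate worm cultures, so the agreement described here may be technical or biological. Regions are named by WS220 coordinates, since no gene annotation of that build was used here.

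The strongest region of NHR-76::GFP occupancy lay on chromosome V from 19212213 to 19212847, with an authors' q value of 1.44e-73, and it ranked 1 among nuclear peaks in replicate 1 and 2 in replicate 2. The next regions were on chromosome II, from 848429 to 849024 (q = 1.30e-53) and from 11618958 to 11620605 (q = 1.69e-35). Each of these lay in both replicate lists, but far lower in replicate 2. The chromosome II region at 848429 ranked 2 in replicate 1 and 779 in replicate 2, and the region at 11618958 ranked 45 and 2390. The widest region of the combined list was on chromosome X from 16929373 to 16931814, spanning 2442 bp with q = 6.04e-34, and it ranked 310 and 533 in the replicates.

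The 20 strongest combined regions that overlapped a peak of both replicates were taken as the named set. They reached down to rank 26 of the combined list, with a weakest q of 2.89e-19, and were 362 to 2442 bp wide. Chromosomes II and V held 6 each, chromosome X held 4, chromosome IV held 3, chromosome III held 1 and chromosome I held 0. All 20 lay among the 2714 strongest nuclear peaks of replicate 1, the number of peaks in the combined list, and 18 lay among the 2714 strongest of replicate 2. Only 6 of them were within the first 100 peaks of both replicates, with tied scores in the order of the authors' peak numbers. Besides the chromosome V region at 19212213, these were on chromosome II from 6887298 to 6887955 (q = 1.86e-32, ranks 20 and 80) and from 5844596 to 5845184 (q = 1.26e-19, ranks 46 and 9), on chromosome IV from 7243920 to 7244302 (q = 1.29e-26, ranks 7 and 29), on chromosome X from 11093546 to 11094596 (q = 4.40e-25, ranks 58 and 1) and on chromosome V from 13565091 to 13565651 (q = 4.72e-22, ranks 24 and 6). At the other extreme, the region on chromosome III from 7718240 to 7718753 (q = 4.99e-29) ranked 25 in replicate 1 and 8662 in replicate 2. The region on chromosome V from 1966867 to 1967375 (q = 2.21e-26) ranked 12 and 11061. Among combined ranks 1 to 250, 27.6% of shifted regions met a replicate 2 peak, so replicate 2 partners of low rank may be chance overlaps. A region on chromosome IV from 2601953 to 2602994 (q = 1.26e-26) was at rank 431 in replicate 1 and 11 in replicate 2, with the highest score of each list. All of the 20 regions carried the highest score of the replicate 1 list, except for the chromosome V region from 5763773 to 5764327 (score 2.57, rank 2593), so the replicate 1 ranks of the others follow the authors' peak numbers. Those of the 20 at rank 29 or better in replicate 2 carried its highest score, so these replicate 2 ranks follow peak numbers as well.

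The combined list held 2714 regions on the 6 nuclear chromosomes, all with q under 0.01. Of these, 21 had q under 1e-20, 129 (4.75%) had q under 1e-10 and 471 (17.4%) had q under 1e-05. Median width was 296.5 bp, with quartiles of 205 and 419 bp; 45 regions were at least 1000 bp wide and 113 were under 50 bp. Together they covered 929 kb, or 0.927% of the chromosome span. The replicate lists were much longer. Replicate 1 held 21140 peaks, of which 21128 were exactly 400 bp wide, and replicate 2 held 25354, of which 25335 were exactly 800 bp wide. Nuclear peaks covered 8.16% of the span in replicate 1 and 16.3% in replicate 2. The scores of the replicate lists were on different ranges, from 0.446 to 3.06 in replicate 1 and from 0.00436 to 2.12 in replicate 2. The highest score was shared by 574 peaks in replicate 1 and by 66 in replicate 2. Scores are therefore compared between replicates only by rank and by correlation, not by their size.

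The 2 replicates were compared to ask how far the ChIP libraries marked the same sites. Of the 21114 nuclear peaks of replicate 1, 5938 (28.1%, exact 95% interval 27.5 to 28.7) overlapped a replicate 2 peak by at least 1 bp. Shifting the replicate 1 peaks along their chromosomes gave a mean of 23.1% ± 0.288 (SD over 100000 shifts) and a maximum of 24.7%, so the overlap was above chance (one-sided permutation test, p = 1e-05, the smallest these shifts can give). The excess came to 6.50% of the peaks that would not overlap by chance. In the other direction, 27.8% of the replicate 2 peaks overlapped replicate 1, against 22.6% for shifted peaks (permutation p = 1e-05). Peaks within a list also overlapped one another, so 1 site can count more than once. The 25332 nuclear peaks of replicate 2 merged into 17194 regions, and the 21114 of replicate 1 into 19371. The overlap was above chance on each of the 6 chromosomes (largest adjusted permutation p = 6e-05), from 27.1% of replicate 1 peaks on chromosome I to 29.8% on chromosome II. The strongest peaks were shared most often. Among the first 250 peaks of replicate 1, 130 overlapped replicate 2, against 23.1% for shifted peaks, and beyond rank 10000 the share was 26.8%. The 2714 strongest peaks of each list had 214 sites of replicate 1 in common with replicate 2 (7.89%, against 2.91% for shifted peaks).

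**Figure D1:**
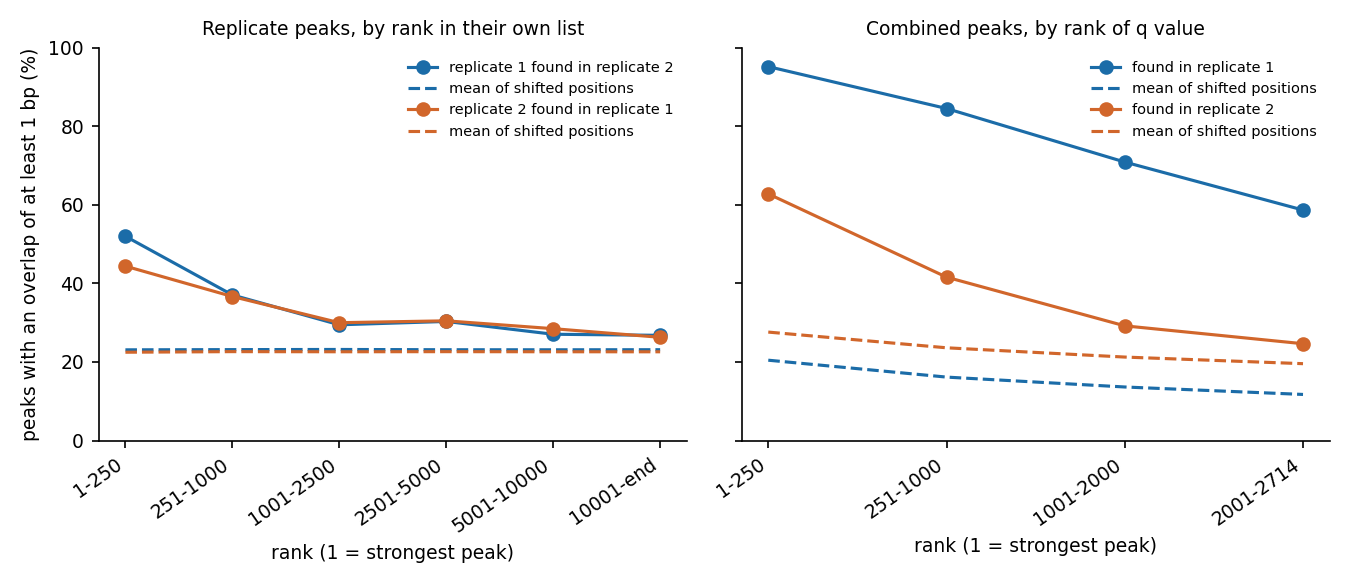
Share of peaks (%, vertical axis) that overlap another list by at least 1 bp, by rank class (horizontal axis, 1 is the strongest peak). The left panel shows replicate 1 peaks found in replicate 2 and the reverse, the right panel combined peaks found in each replicate, and dashed lines give the mean of shifted positions. The first 250 combined peaks were found in replicate 1 for 95.2% and in replicate 2 for 62.8%, while replicate peaks beyond rank 10000 overlapped the other replicate for 26.8% (replicate 1) and 26.3% (replicate 2), above the 23.1% and 22.6% of the dashed lines.

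Across the 5938 overlapping pairs, scores of the 2 replicates were weakly related, with Spearman's rho of 0.07 and Pearson's r of 0.11 (permutation p = 1e-05 for each; adjusted p for rho 3e-05 over 9 relations). These are correlations across peaks, which are not independent replicates. Many pairs may be chance partners, since 28.1% of replicate 1 peaks overlapped replicate 2 against 23.1% for shifted peaks. Chance partners would weaken the correlation, so it does not measure agreement at sites marked by both libraries. Within chromosomes, rho ran from 0.01 on chromosome V (adjusted permutation p = 0.735) and 0.05 on chromosome IV (adjusted permutation p = 0.105) to 0.09 on chromosome II (adjusted permutation p = 0.00724). Among the 214 pairs in the 2714 strongest peaks of both lists, rho was 0.27 (permutation p = 8e-05). There the overlap was 7.89% against 2.91% for shifted peaks, so chance partners may be a smaller part of these pairs.

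The combined list followed replicate 1 more closely than replicate 2. Of the 2714 combined regions, 2000 (73.7%, exact 95% interval 72.0 to 75.3) overlapped a replicate 1 peak, against 14.5% for shifted regions, and 937 (34.5%, interval 32.7 to 36.3) overlapped a replicate 2 peak, against 22.1% for shifted regions (permutation p = 1e-05 for each). Both replicates held 742 regions (27.3%, interval 25.7 to 29.1), against 4.04% for shifted regions (permutation p = 1e-05). Replicate 1 alone held 1258 (46.4%), replicate 2 alone 195 (7.18%), and 519 (19.1%) overlapped neither. Peaks of replicate 2 are wider, which raises their chance overlap. Among the 100 strongest combined regions, 98 lay in replicate 1, 78 in replicate 2 and 76 in both. Among the 714 regions ranked 2001 to 2714, 58.7% lay in replicate 1 and 24.6% in replicate 2, where shifted regions gave 11.7% and 19.6%. For the 742 regions in both, −log10 q was related to the replicate 1 score with rho of 0.48 and to the replicate 2 score with rho of 0.18. The difference was 0.30 (95% bootstrap interval over regions 0.21 to 0.39). By the shifted regions, chance overlaps may be a larger part of the partners in replicate 2 than in replicate 1. They would weaken the replicate 2 rho, and the interval does not cover this.

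Broad regions, examined as a class after the widths had been seen, overlapped the replicates above chance, as the list as a whole did (73.7% against 14.5% in replicate 1 and 34.5% against 22.1% in replicate 2). Of the 45 combined regions of at least 1000 bp, 43 (95.6%) overlapped replicate 1 and 35 (77.8%) overlapped replicate 2, against 31.6% and 37.8% for the same regions shifted (permutation p = 1e-05 for each); they were not compared with narrower regions of equal strength. The widest after the chromosome X region at 16929373 were on chromosome I from 7866004 to 7868159 (2156 bp, q = 8.30e-09) and on chromosome X from 10077446 to 10079407 (1962 bp, q = 8.87e-22), the latter with no replicate 2 peak. A region on chromosome X from 12517220 to 12519124 (1905 bp, q = 4.53e-16) ranked 166 in replicate 1 and 2887 in replicate 2.

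Across chromosomes, chromosome I stood apart in the combined list. It held 93 of the 2714 regions (3.43%, exact 95% interval 2.77 to 4.18), where its share of the span of 15.02% would give 407.6 (exact binomial test, adjusted p = 7.44e-87 over 6 chromosomes). That is 6.18 regions per Mb, against 28.8 to 35.1 per Mb on the other 5 chromosomes. The replicate lists did not show this. Chromosome I held 15.7% of the 2714 strongest peaks of replicate 1 (interval 14.3 to 17.1) and 14.6% of those of replicate 2 (interval 13.3 to 15.98), and both intervals include its share of the span (exact binomial test, adjusted p = 0.384 and 0.649). The strongest combined region on chromosome I, from 7660851 to 7661608, had q = 1.55e-14 and rank 54. The X chromosome held 530 combined regions (19.5%, interval 18.1 to 21.1), above its 17.7% share of the span (exact binomial test, adjusted p = 0.0153), but with chromosome I left out its 20.2% was slightly below the expected 20.8% (exact binomial test, adjusted p = 0.809). Among the 2714 strongest peaks of a single replicate, the X share was 20.0% in replicate 1 (exact binomial test, p = 0.00196) and 18.6% in replicate 2 (p = 0.227). Without chromosome I, X remained above its share of 20.8% in replicate 1, among the 2714 strongest peaks (23.7%, exact binomial test, adjusted p = 0.00202) and in the full list (21.8%, adjusted p = 0.00196). In replicate 2 the shares without chromosome I were 21.7% (exact binomial test, adjusted p = 0.434) and 20.95% (adjusted p = 0.573). In the full combined list chromosome III was above its share in both cases, with 484 regions (17.8% against 13.7%, exact binomial test, adjusted p = 8.13e-09, and 18.5% against 16.2% without chromosome I, adjusted p = 0.00872). It did not pass the test among the 1357 combined regions of lowest q without chromosome I (18.5%, exact binomial test, adjusted p = 0.134), or among the 2714 strongest peaks of replicate 1 (15.03%, adjusted p = 0.0816) and of replicate 2 (15.2%, adjusted p = 0.0955). It passed in the full lists of replicate 1 (14.4%, exact binomial test, adjusted p = 0.0172) and replicate 2 (14.3%, adjusted p = 0.0265). Without chromosome I it also passed among the 2714 strongest peaks of replicate 1 (17.8% against 16.2%, exact binomial test, adjusted p = 0.0415), but not of replicate 2 (adjusted p = 0.0987). Chromosomes II and IV were above their share with chromosome I included (exact binomial test, adjusted p = 0.00539 and 0.00441) and not without it (adjusted p = 0.980 for each). The replicates went the other way for chromosome IV, which lay below its 17.4% share of the span in the full lists of replicate 1 (16.2%, exact binomial test, adjusted p = 4.43e-06) and replicate 2 (16.7%, adjusted p = 0.0193) and among the 2714 strongest peaks of replicate 1 (14.9%, adjusted p = 0.00216), while the strongest of replicate 2 held 17.1% (adjusted p = 0.649). Among the 1357 combined regions of lowest q, chromosome IV held 18.3% (exact binomial test, adjusted p = 0.391). The replicate shares of chromosome II were 15.5% to 15.8%, against 15.2% of the span, and passed the test in neither the full lists nor the 2714 strongest peaks (adjusted p from 0.170 to 0.649). Chromosome V held 22.2% of combined regions, against 20.9% of the span (exact binomial test, adjusted p = 0.0847). Without chromosome I it held 23.01%, against 24.6% (exact binomial test, adjusted p = 0.165). In the replicates, chromosome V lay below its share of the span. It held 18.6% of the 2714 strongest peaks of replicate 1 (exact binomial test, adjusted p = 0.00851). For replicate 2 this was 18.8% (exact binomial test, adjusted p = 0.0456). It held 19.98% of the full replicate 1 list (exact binomial test, adjusted p = 0.00424). For the full replicate 2 list this was 20.4% (exact binomial test, adjusted p = 0.127). These tests treat regions as independent, although neighbouring regions cluster.

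**Figure D2:**
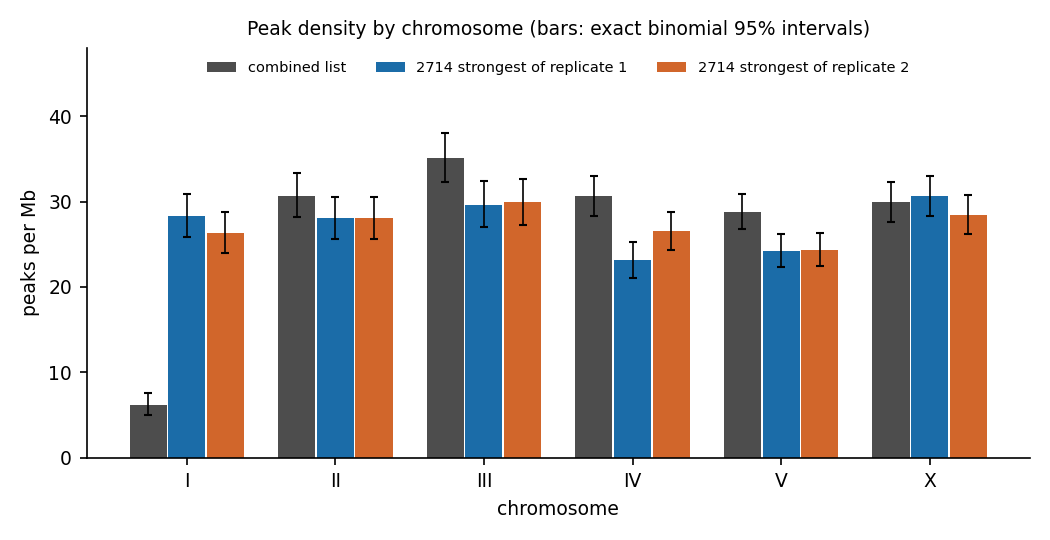
Peaks per Mb (vertical axis) on each nuclear chromosome (horizontal axis) for the combined list and for the 2714 strongest nuclear peaks of each replicate; error bars are exact binomial 95% intervals. Chromosome I has 6.18 combined regions per Mb, while the strongest replicate peaks there number 28.3 and 26.3 per Mb.

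The difference on chromosome I varied with rank in replicate 1, which was examined after the low number there had been seen. The highest score was shared by 574 replicate 1 peaks, of which 25 were mitochondrial. Ranks 1 to 300 and most of ranks 301 to 600 thus differ by the authors' peak numbers, not by score. Of the replicate 1 peaks at ranks 1 to 300, 27 of 35 on chromosome I (77.1%) overlapped a combined region, against 255 of 265 (96.2%) elsewhere (Fisher's exact test, two-sided, adjusted p = 0.000293 over 6 rank classes). At ranks 601 to 1200 the shares were 6 of 100 and 195 of 500 (39.0%; Fisher's exact test, adjusted p = 5.83e-12). The change with rank was not steady. The ratio of the share on chromosome I to that elsewhere was 0.802 at ranks 1 to 300, 0.398 at ranks 301 to 600 and 0.154 at ranks 601 to 1200, then 0.279 and 0.264 in the next classes, up to rank 5000, and 0.158 beyond it.

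**Figure D3:**
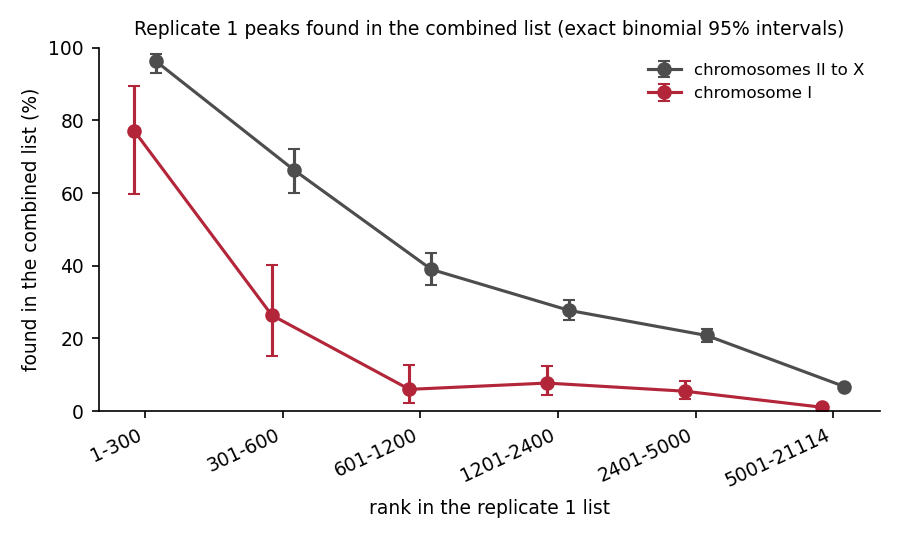
Share of replicate 1 peaks (%, vertical axis) that overlap a combined region, by rank class in replicate 1 (horizontal axis), for chromosome I and for the other 5 nuclear chromosomes; error bars are exact binomial 95% intervals. The share on chromosome I is 77.1% at ranks 1 to 300, and 6 of 100 peaks at ranks 601 to 1200, against 96.2% and 39.0% elsewhere.

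Along chromosomes, combined regions were more frequent in the middle than toward the ends, a comparison chosen after the positions had been seen. The middle 60% of each chromosome held 1848 of 2714 regions (68.1%, interval 66.3 to 69.8; exact binomial test, p = 2.84e-18). By chromosome, the share ran from 58.1% on chromosome I (54 of 93, exact binomial test, adjusted p = 0.751) and 65.7% on the X chromosome (adjusted p = 0.00934) to 72.1% on chromosome V (adjusted p = 3.75e-09), and differences between chromosomes were not tested. In the full replicate lists the shares lay on opposite sides of 60%, with 62.6% of replicate 1 peaks in the middle and 58.5% of replicate 2 peaks (exact binomial tests, p = 3.39e-15 and 9.61e-07), and they differed from each other (Fisher's exact test, two-sided, p = 7.02e-20, odds ratio 1.19). The lower share in replicate 2 did not pass the test among its 2714 strongest peaks (58.8%, exact binomial test, p = 0.196), on chromosome V (59.4%, adjusted p = 0.492) or on the X chromosome (59.98%, adjusted p = 0.988). The higher share in replicate 1 did not pass on the X chromosome (60.2%, exact binomial test, adjusted p = 0.768).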

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

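The tests in this part were chosen after the results were seen, except the one on combined regions outside the replicate 1 list, whose prediction was written beforehand.

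Mitochondrial peaks lay outside the nuclear comparisons and are a signal in data the report did not use. Replicate 1 listed 26 and replicate 2 listed 22, while the combined list had 0. They took 17 of the first 20 peak numbers in each replicate list. In replicate 1 they covered 53.2% of the mitochondrial span of 13403 bp and in replicate 2 76.7%, against 8.16% and 16.3% of the nuclear span. With a single peak at each site, 3 separate sites would cover 8.95% of the span at the width used in replicate 1 and 17.9% at that of replicate 2. The coverage seen was higher in both lists. This does not test the number of sites, since 26 and 22 peaks are already more than 1 peak at each of 3 sites would give. Several adjoining peaks at 1 site would also raise the coverage. A surplus of mitochondrial reads along the molecule and binding at separate sites cannot be told apart from this coverage. The peaks have a fixed width and the molecule is short. The input libraries were not analysed here.

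The low number of combined regions on chromosome I is a second pattern. Less NHR-76::GFP binding, by as much as the combined list shows, is argued against by replicate 1, where chromosome I held 15.7% of the 2714 strongest peaks, although its 35 of the first 300 (11.7%, exact 95% interval 8.26 to 15.9) leave room for a smaller deficit at strong sites. Misplaced coordinates are argued against by the 87.1% of combined regions on chromosome I that overlapped replicate 1, above the 73.2% elsewhere (Fisher's exact test, two-sided, p = 0.00249). A loss of regions at one rate for all replicate 1 ranks would have kept 8.99 of the 35 chromosome I peaks at ranks 1 to 300. Of these peaks 27 were kept, above the highest of 100000 simulated draws, 21. Those ranks shared the highest score with most of ranks 301 to 600, where 14 of 53 chromosome I peaks were kept. The test therefore concerns the authors' peak order, not the score. A candidate explanation is a stricter call on chromosome I when the combined list was made: at replicate 1 ranks 1 to 600, combined regions on chromosome I had a median q of 0.000112 (40 regions), against 3.65e-06 elsewhere (407 regions), a difference of -1.49 in median −log10 q, chromosome I minus the others (permutation test, two-sided, p = 0.0212). Over all combined regions the medians lay close together, at 0.00169 on chromosome I (93 regions) and 0.00158 elsewhere (2621 regions). The share of chromosome I was also similar among the 1357 regions of lowest q (3.39%) and in the whole list (3.43%), which a loss without regard to strength would give as well, so the stricter call remains a candidate only. Whether that came from scaling against input or from fewer reads on that chromosome cannot be read from peak lists.

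The low overlap of the replicates is the third pattern. A coordinate offset between the lists is argued against by the distances between peak centres: among the 2714 strongest peaks of each list, 81 pairs lay within 100 bp, and the highest other bin of 200 bp held 44. If replicate 2 contributed nothing, combined regions outside the replicate 1 list were predicted to overlap replicate 2 no more often than shifted regions. Of these 714 regions, 27.3% overlapped replicate 2, against 20.5% for shifted regions (permutation p = 1e-05). This cannot decide the question, because a list made from replicate 1 alone would also hold sites that both libraries share. The replicate 1 peaks themselves overlapped replicate 2 at 28.1%, against 23.1% for shifted peaks. Weaker enrichment in replicate 2 is consistent with the 250 strongest combined regions, of which 94.0% beyond chance lay in replicate 1 and 48.6% beyond chance in replicate 2. An unequal number of reads, or an unequal weight of the libraries in the combined list, would give the same values and stays open. No biological difference between the replicates is named by the design, so none was tested.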

How the results depend on the processing

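No paired analysis was possible because no peak list belongs to the input libraries that share replicate numbers with the ChIP libraries. Of 33 alternatives, 22 kept direction and side of the threshold, 2 kept direction but did not pass it, and 3 reversed direction. The other 6 were sizes of the lists, which had no test. The overlap of replicate 1 with replicate 2 and the score correlation did so under every alternative run, with overlaps of 7.65% to 28.3% and excesses over chance of 2.71% to 6.80%, and rho of 0.06 to 0.27. The share of combined regions in both replicates was 4.83% when only the 2714 strongest replicate peaks counted, and 36.8% among the 1357 combined regions of lowest q; with 1 replicate it was 34.5% to 73.7%, above chance in each. The X chromosome share turned to 20.2%, below the expected 20.8%, without chromosome I, and with the strongest peaks of 1 replicate in place of the combined list it was 18.6% (replicate 2, exact binomial p = 0.227) to 20.0% (replicate 1). The chromosome I share on the same peaks was 14.6% (replicate 2) to 15.7% (replicate 1, above its 15.02% of the span), against 3.43%. The share in the middle 60% was 58.8% (replicate 2, below 60%, exact binomial p = 0.196) to 66.1% (replicate 1), and 68.4% without chromosome I. The cause was not tested for the X chromosome and the middle share; explanations of the chromosome I share were tested on their own. Every alternative on the chromosome I and middle shares, without chromosome I, on the shift distance, or on combined regions with 1 replicate was chosen after seeing the data. By construction, peaks above the median rank numbered 10557, 12666 and 1357 in replicate 1, replicate 2 and the combined list, and the merged peaks covered 8176468, 16373049 and 929496 bp. The alternatives on promoters, gene lists, motifs and noncoding genes, and the comparison of X with its share of transcription start sites, were not run because no annotation of the WS220 build was used. Read depth is unknown, so the number of regions that deeper libraries would add cannot be estimated.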

Other observations

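The tests in this part were chosen after the data were seen, and they report values without an explanation, for regions chosen after their values were seen. Combined regions clustered along the chromosomes. Of 2708 gaps between neighbours, 259 (9.56%) were under 1000 bp, against a mean of 108 and a maximum of 146 in 1000 random placements (permutation p = 0.000999, the smallest they can give). The densest window of 20 kb was on chromosome IV from 8520001 to 8540000, with 8 regions and a best q of 5.00e-22; 6 of the 8 overlapped replicate 1 and 4 overlapped replicate 2. Windows on chromosome II from 14040001 to 14060000 (best q = 6.92e-09) and on chromosome V from 720001 to 740000 (best q = 2.68e-14) held 7 each. Against 10000 uniform random placements, a permutation test of positions gave p = 0.0018 for a window with 8 regions anywhere and p = 0.0169 for one with 7. These placements keep neither the higher density in chromosome middles nor the splitting of a broad region into several calls. A window with 6 regions anywhere was not unusual in the placements (permutation p = 0.178). There were 5 such windows among the 8 densest, and whether that many would arise by chance was not tested.

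Each of the 100 strongest combined regions overlapped a peak of at least 1 replicate, but some were absent from the other or met only a peak of low rank. The region on chromosome IV from 13318692 to 13319125 (q = 2.00e-23, rank 13) met only a replicate 1 peak at rank 16853 and no replicate 2 peak. The region on chromosome II from 8819222 to 8820830, 1609 bp wide with q = 5.11e-19 and rank 27, overlapped no replicate 1 peak and a replicate 2 peak at rank 1329. The region on chromosome III from 312883 to 313263 (q = 8.21e-13, rank 80) overlapped only a replicate 2 peak at rank 20656. The other 98 of the 100 strongest regions overlapped replicate 1, with 89 of them among its 2714 strongest peaks, and 44 of the 100 were among the 2714 strongest of replicate 2.

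Some regions ranked higher in replicate 2 than in replicate 1. On chromosome IV, the region from 9511103 to 9511986 (q = 2.75e-12) ranked 121 in replicate 2 and 4745 in replicate 1. On chromosome I, the region from 2084862 to 2085409 (q = 7.02e-11) ranked 10 in replicate 2 and 710 in replicate 1. On chromosome V, the region from 9095536 to 9096011 (q = 2.89e-19) ranked 7 in replicate 2 and 246 in replicate 1. It carried the highest score of both lists, however, so its ranks differ by the authors' peak numbers only.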
